A study of Sus scrofa with 4 samples.

How the data were processed

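Cells of whole pig testis (Sus scrofa) at 7, 30, 60 and 90 days were profiled with 10x Chromium 3′ chemistry version 3, in 1 library per age, and read as pairs of 150 bases on a NovaSeq 6000. The deposited files hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized. The submitters' processing notes name bcl2fastq, Cell Ranger and Scanpy 1.7.1, with genome build Sscrofa11.1, and the version of Cell Ranger is 5.0.1 per the file headers. Cell types were rebuilt from the counts, since no cell annotation was used here. The labels name 86453 captured cells, and the 4 files hold 69602 barcodes, of which 55798 passed the filters below and 48922 were used. The files list 31908 features. Of these, 16508 carry a gene symbol and 15400 only an Ensembl identifier, and 825 of the latter were given a symbol from a reference table of gene names. That table holds 15029 of the identifiers and gives another name for 254 of 14204 named features, where the symbol in the file was kept. Of the 453 genes in lists and marker sets, 37 had no feature of that symbol.

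The 7-day library held 15896 barcodes and 96133720 counts, the 30-day library 19373 and 77992845, the 60-day library 16839 and 45717373, and the 90-day library 17494 and 64372068. Barcodes were kept with at least 1000 UMIs, at least 500 detected genes and at most 15% of UMIs from the 13 mitochondrial genes, which left 13847, 17285, 11991 and 12675 in order of age. The minimum of 1000 UMIs fell on the libraries unequally, with 1367, 1743, 4498 and 2606 barcodes below it. Doublets were called per library with Scrublet as built into Scanpy, with an expected rate of 0.8% per 1000 barcodes and its automatic threshold. It removed 774 cells (5.59%), 1781 (10.3%), 3459 (28.8%) and 862 (6.80%) in order of age.

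The cells of all libraries were clustered together without integration, because library and age coincide and integration would remove both. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with library as batch, and 30 principal components and 15 neighbours went into Leiden clustering at resolution 1 with seed 0. The tools were Python 3.11.15, Scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The 40 clusters were named from 17 marker sets, at least 3 detected markers each. Samples, comparisons, marker sets, gene lists, the rule for named genes and most of the alternatives listed below were fixed before the data were examined. The thresholds of the naming score and 3 naming rules were set after seeing the data. Clusters with a median depth under 60% of their libraries' and a weak score stayed unnamed as shallow and mixed. Stromal markers did not count as rivals of the myoid name. A cluster with vascular beside myoid markers was kept out of the myoid class.

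Raw counts were summed per library and class, and CPM was taken of the sum. The main comparison was 90 against 7 days, or the latest against the earliest library with at least 100 cells of the class, followed by the 3 steps between neighbouring ages. With 1 library per age no test was run. CPM values carry exact Poisson intervals, ratios of CPM exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95%. A gene with no count on one side was set against a floor of 3 counts over the class. Named genes were the 10 largest increases and 10 largest decreases per niche class, and the 3 largest of each per step, ranked by the interval bound nearest to no change. They needed a symbol and at least 50 CPM in the higher library, and at least as much there in the class as in all other cells of that library. Mitochondrial, ribosomal protein and haemoglobin genes were left out. For 21 gene lists, members with at least 10 counts in both libraries together were counted as higher or lower when they differed by at least 1.5 times with an interval that excluded no change. The list median was placed among 10000 random lists matched on expression in 20 bins, as a description of these libraries.

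The interval method was tested on simulated data, with Poisson counts drawn from the pooled profile of each niche class at the real depths and 200 genes changed by 2 or 4 times. Intervals covered the set ratio for 96 to 99% of the changed genes and for 96.0 to 96.8% of the others. The draws held no spread between animals, libraries or cells, so this coverage is for counting error only. The shares, the list results and the 60 genes named in the main comparisons of the niche classes were computed again without doublet removal, with at least 1000 genes and at most 10% mitochondrial UMIs per cell, at resolutions 0.5 and 2, and with each library clustered on its own. Other alternatives, for lists and named genes, were the mean over cells of counts per 10000, each cell thinned to 2000 UMIs, TMM factors from edgeR 4.0.16 in R 4.3.3, subtraction of 10% free RNA, and, for lists, at least 100 counts per gene. Genes named per step and the other classes were not computed again. A pair of alternatives was added after seeing the data: removal of only the expected share of doublets in every library, and joint clustering without the 60-day library. Positions are those of the RefSeq annotation of the same build.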

Results

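The series follows the niche cells of the pig testis, the somatic cells that surround and feed the germ cells, at 7, 30, 60 and 90 days of age. Each age was 1 library of single cells, so no difference between ages has a replicate check, and age cannot be told apart from library. All intervals are exact 95% intervals that cover counting error only. Expression is in counts per 1000000 (CPM) of the summed counts of a cell class, and "higher" and "lower" give the size of a ratio, not a tested change. Classes were rebuilt from marker genes, so they are called Sertoli-like, Leydig-like and so on. After the filters, 13073 cells of the 7-day, 15504 of the 30-day, 8532 of the 60-day and 11813 of the 90-day library were used.

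The makeup of the 4 libraries moved from mostly Sertoli-like cells at 7 days to many germ cells at 90 days. Sertoli-like cells, the somatic cells that line the tubules, made up 52.4% (51.6 to 53.3%) of the cells at 7 days and 38.2% (37.4 to 38.9%) at 30 days. They made up 31.9% (30.9 to 32.9%) at 60 days and 19.98% (19.3 to 20.7%) at 90 days. The 60-day share depended on the treatment of doublets and of shallow cells. Doublet removal took 28.8% of that library's cells, which had a median of 1662 counts against 2745.5 in the cells kept. The share was 50.5% with the stricter cell filter, 59.4% with no cells removed as doublets and 69.1% with only the expected share removed, and in the last pair of settings no shallow mixed clusters were kept apart. The share at 90 days was 11.5% with each library clustered on its own.

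Spermatocyte-like cells, which are in meiosis, and spermatid-like cells, the haploid cells that follow, were assigned at 90 days only in the main setting, at 5.31% (4.91 to 5.73%) and 10.99% (10.4 to 11.6%). The exact intervals of the younger libraries, with no such cell named, reach up to 0.0282% at 7 days, 0.0238% at 30 days and 0.0432% at 60 days. Other settings named spermatocyte-like cells at 60 days, 88 (1.03%) with each library clustered on its own and 53 (0.621%) at resolution 2, but spermatid-like cells at 90 days only. The summed CPM of 10 spermatid markers over the whole library was 8.06, 11.6, 6.31 and 4077 at the 4 ages in order. Another 14.9% (14.3 to 15.6%) of the 90-day cells were germ cells whose stage, spermatogonia or spermatocyte, was not resolved. So were 6 cells (0.0387%) at 30 days and 44 (0.516%) at 60 days, which the intervals of the younger libraries do not cover. Spermatogonia-like cells, the germline stem and progenitor cells, made up 4.12%, 6.29%, 1.99% and 2.997% at the 4 ages. Their 90-day share ranged from 2.997% to 17.9% over the settings, whereas all germ cells together stayed between 34.1% and 36.0% at that age. At 60 days the spermatogonia-like share ranged from 1.66% to 12.8% and that of all germ cells from 2.13% to 13.8%.

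Leydig-like cells, the cells that make testosterone, were between 2.14% and 4.24% of the cells at every age. Their share was 3.81% (3.49 to 4.15%) at 7 days and 2.51% (2.24 to 2.81%) at 90 days. With the stricter cell filter the 90-day share was the higher one by 0.346 percentage points. Peritubular myoid-like cells, the contractile cells around the tubules, were 0.107% (0.059 to 0.180%) at 7 days, with 14 cells. They were 20.2% (19.6 to 20.9%) at 30 days and 10.3% (9.69 to 10.99%) at 60 days, in a cluster whose mean marker fold was higher for stromal than for myoid markers, and 5.55% (5.15 to 5.98%) at 90 days. The 60-day value ranged from 0.492% to 10.3% over the settings. A cluster with 0.520%, 0.632%, 0.398% and 2.15% of the libraries in order of age, 68 cells at 7 days, was kept out of this class as vascular smooth muscle-like by a rule set after the data were seen, although it scored 3.38 as myoid and 1.81 as pericyte or vascular (mean log2 folds over the markers). Interstitial stromal-like cells were 26.6%, 18.7%, 12.2% and 17.9% of the libraries in order of age. A pair of shallow clusters with mixed markers was kept out of all classes and held 0.451%, 0.813%, 31.7% and 0.102% of the cells in that order. Both scored highest as Sertoli, at a mean log2 fold of 0.793 and 0.898 over the markers, beside 0.882 in the cluster of the 90-day Sertoli-like cells. The median counts per used cell were 5100 at 7 days, 2898 at 30 days, 2745.5 at 60 days and 2549 at 90 days.

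**Figure D1:**
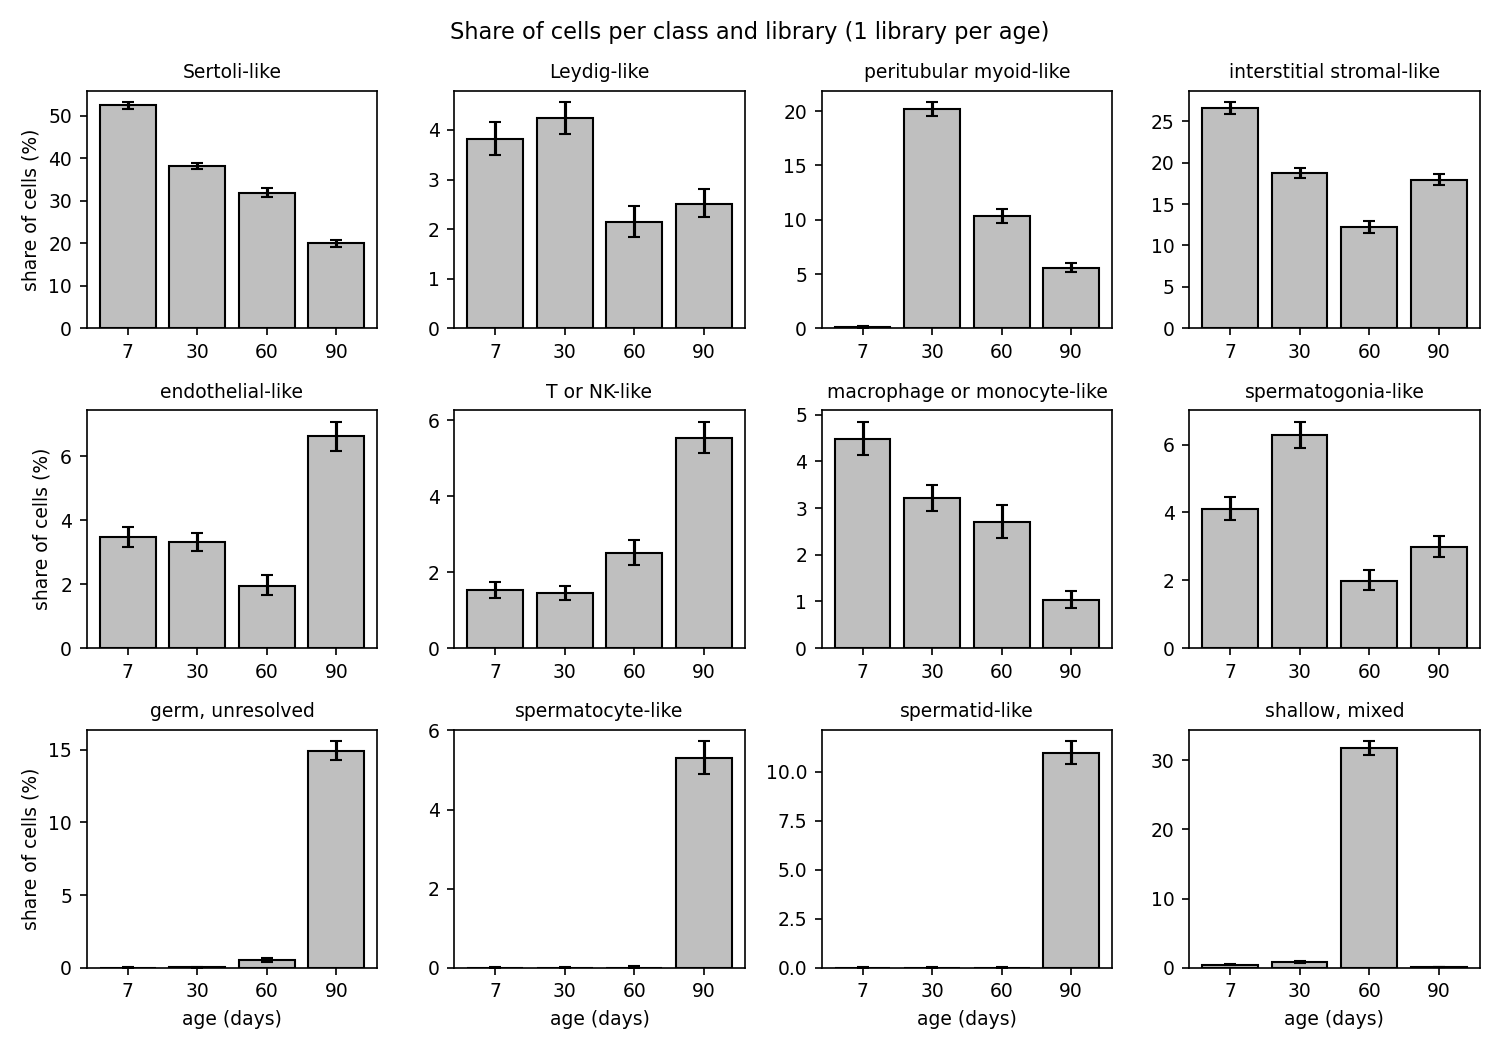
Share of the used cells of each library (percent, y axis) for 12 cell classes, 1 panel each with its own scale, against age in days (x axis, ages drawn at equal steps, 1 library each). Bars are shares, and error bars are exact 95% binomial intervals that cover counting error only. The Sertoli-like share runs from 52.4% at 7 days to 19.98% at 90 days.

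In Sertoli-like cells, 6 of 11 genes of the immature Sertoli cell and 17 of 20 genes of dividing cells were lower in the 90-day than in the 7-day library, and 8 of 14 genes that handle retinoic acid were higher. AMH, the hormone that immature Sertoli cells secrete, was 2517 CPM at 7 days, 1017 at 30 days, 989 at 60 days and 164 at 90 days, a log2 ratio of −3.94 (−4.00 to −3.88) for 90 against 7 days. CCND2, a cyclin that drives cells from G1 into S phase, was 1042 CPM at 7 days and 7.40 at 90 days, a log2 ratio of −7.14 (−7.42 to −6.86), or −12.20 with 10% free RNA subtracted. CRABP1, which binds retinoic acid in the cytoplasm, was 4.37 CPM at 7 days and 972 at 90 days, a log2 ratio of 7.80 (7.60 to 8.004). The comparison set 2360 cells with 14455091 counts against 6856 cells with 46213471 counts.

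The clusters behind the name differed with age, with mostly separate clusters for 7, 30, 60 and 90 days, and the 90-day cluster took its name from the mean fold of its markers. Several genes named here, AQP8, CLEC12B, SEPTIN14 and ALDH1A1 among them, also lead that cluster, and TNNI1, AMH and INHA lead a cluster made mostly of 7-day cells. The median log2 ratio over the 19864 measured genes was 0.49, and TMM scaling moved every ratio by −0.58, so sizes below are best read against that shift. Ribosomal protein genes took 14.7% of the Sertoli-like counts at 7 days and 11.2% at 90 days.

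The 10 genes with the largest increase by the fixed rule were AQP8, CLEC12B, SEPTIN14, TBATA, PNMT, TMPRSS15, NAALAD2, MCF2, CRABP1 and DYNC1I1. AQP8, a water channel encoded on chromosome 3 (21493564 to 21503778 in build Sscrofa11.1), was 0.0866 CPM at 7 days and 291 at 90 days, a log2 ratio of 11.71 (10.36 to 13.59). CLEC12B, a C-type lectin receptor, was 0.498 CPM at 7 days, 50.4 at 30 days, 53.3 at 60 days and 687 at 90 days. TBATA and PNMT, the latter the enzyme that makes adrenaline, had 1 count each at 7 days, and their log2 ratios were 11.31 (8.83 to 16.62) and 11.21 (8.73 to 16.51). TBATA is also a leading gene of a spermatid-like cluster, and its log2 ratio in all other cells of the same libraries was 7.17. DYNC1I1, a dynein intermediate chain, had a log2 ratio of 8.35 in Sertoli-like cells and 0.06 in all other cells.

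Among the largest decreases were TNNI1, NXNL2, CCND2, SCN7A, KCNK12, CD44, SPON2, SMOC1 and CDC42EP5. TNNI1, the troponin I of slow muscle fibres, was 252 CPM at 7 days and had no count at 90 days, so it was at least 1215-fold lower, against a floor of 3 counts over the class. NXNL2 had 3 counts at 90 days and a log2 ratio of −8.94 (−11.22 to −7.40). CD44, a hyaluronan receptor, had a log2 ratio of −7.13, and SCN7A, a sodium channel gene, −7.18. SPON2, a secreted matrix protein, was highest at 30 days at 267 CPM and was 0.346 CPM at 90 days.

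Of the 11 measured immature Sertoli genes, 6 were at least 1.5 times lower at 90 days and 1 was higher, with a list median of −1.05, or −1.60 over the 8 members with at least 100 counts. With TMM factors 8 were lower and 0 higher, with a median of −1.63. The median of −1.05 lay at percentile 0.08 of 10000 random lists matched on expression, and 5 members also served as markers of the class. INHA, the inhibin alpha subunit, had a log2 ratio of −2.84 and was 4155 CPM at 7 days and 581 at 90 days. INHBB, an inhibin and activin beta subunit, had −2.15, and DHH, the hedgehog ligand of Sertoli cells, −1.05. DES, the intermediate filament gene of muscle, was the higher member at 1.17. SOX9, the transcription factor of Sertoli cell fate, was 250 CPM at 7 days and 371 at 90 days, a log2 ratio of 0.57, which is no more than the shift of TMM scaling.

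Of 20 cell cycle genes, 17 were lower and 1 was higher, with a median of −1.96, or −1.08 as the mean over cells. The median was 0.59 in all other cells, pooled with their changing mix of classes. By class it was −1.22 in Leydig-like, −1.15 in pericyte-like or vascular smooth muscle-like and −0.92 in spermatogonia-like cells. It was −0.83 in T or NK-like, −0.72 in interstitial stromal-like and −0.66 in endothelial-like cells, but 0.66 in macrophage or monocyte-like cells. In Sertoli-like cells UBE2C and CENPF, which act in mitosis, had −3.80 and −3.43. TOP2A, a DNA topoisomerase of dividing cells, was 364 CPM at 7 days, 77.0 at 30 days, 74.0 at 60 days and 50.6 at 90 days. Of 14 basement membrane genes, 11 were lower and 2 were higher, with a median of −1.27. COL4A2, a type IV collagen chain, had −3.42, LAMB1, a laminin chain, −2.94, and LAMA4, another laminin chain, 2.24. Immediate early genes, which respond within minutes to stimuli and also to tissue dissociation, were lower in 13 of 16 members, or 15 with TMM factors. Their median was −1.46 in this class and −1.28 in all other cells, pooled with their changing mix of classes. ATF3 and NR4A1 had −3.73 and −3.87. ATF3, EGR4 and HOMER1 are leading genes of the 60-day Sertoli-like cluster. Of 16 interferon response genes, 12 were lower and 1 was higher, with a median of −1.46 here. The median was −1.92 in all other cells, pooled with their changing mix of classes. Yet each other class compared at these ages lay above −1.46. They ran from −1.35 in macrophage or monocyte-like to −0.83 in endothelial-like and 0.37 in Leydig-like cells. With 10% free RNA subtracted 7 were lower and 2 higher in Sertoli-like cells, with a median of −0.59. B2M, the light chain of MHC class I, had −2.80.

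Genes of retinoid handling and of cholesterol synthesis were mostly higher. Of 14 retinoid pathway genes, 8 were higher and 3 lower with a median of 1.47, and 7 and 5 with a median of 0.89 under TMM factors. ALDH1A1, an enzyme that makes retinoic acid, was 26.0 CPM at 7 days, 106 at 30 days, 23.4 at 60 days and 808 at 90 days. RARB, a retinoic acid receptor, had 3.91, whereas CYP26B1, which breaks retinoic acid down, had −2.48 and CRABP2 −4.17. Of 22 genes of cholesterol synthesis and uptake, 15 were higher and 1 lower with a median of 0.79, but 5 were higher and 4 lower with TMM factors, where the median was 0.21. SC5D and CYP51A1, late enzymes of sterol synthesis, had 1.63 and 1.26, and IDI1, an isoprenoid enzyme, −0.97.

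Junction genes of the blood-testis barrier had no single direction, with 4 of 13 members higher and 2 lower and a median of 0.39, against 2 and 4 and −0.19 with TMM factors. The median was 0.14 with each library clustered on its own, 0.12 with free RNA subtracted and 0.040 as the mean over cells. ESPN, an actin-bundling protein of the ectoplasmic specialization, had 3.54, and 4.06 in all other cells. GJA1, the gap junction protein connexin 43, had 1.61. Of 14 hormone receptor genes, 4 were higher and 5 lower, and 2 and 7 with TMM factors. ESR1, an oestrogen receptor, had 2.90, and AMHR2, the receptor of AMH, −3.26. FSHR, the receptor of the pituitary hormone FSH, had −0.41. Among 23 genes of the TGF-beta superfamily 5 were higher and 10 lower, or 3 and 13 with TMM factors, with TGFB2 at 5.03 and BMP2 at −6.03. Of 13 genes of Sertoli support of germ cells, 5 were higher and 5 lower, or 3 and 6 with TMM factors. KITLG, the ligand of the KIT receptor, had 1.15, and GDNF, the stem cell growth factor, −2.53.

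Between neighbouring ages the largest increases were CLEC12B, PRND and CRABP1 from 7 to 30 days, KRT8, MARCO and GABRB2 from 30 to 60 days, and MRC1, SULT4A1 and ALDH1A1 from 60 to 90 days. KRT8, MARCO and GABRB2 were low again at 90 days, at 3.32, 3.25 and 2.84 CPM. PRND, the prion-like protein doppel, was 3.14 CPM at 7 days and 194 at 30 days. MRC1, a mannose receptor known from macrophages, had a log2 ratio of 6.95 in the last step, and −0.51 in all other cells. The largest decreases were KRT8, NPTX2 and TNNI1 in the first step, SPINK5, FAM167B and XG in the second, and NXNL2, SPON2 and SCN7A in the last. SPINK5, a serine protease inhibitor, was 273 CPM at 30 days and 1.32 at 60 days.

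KRT8, a keratin of simple epithelia on chromosome 5 (18172423 to 18180277), did not run one way with age. In Sertoli-like cells it was 149 CPM (145 to 153) at 7 days, 3.29 (2.64 to 4.04) at 30 days, 257 (249 to 265) at 60 days and 3.32 (2.45 to 4.40) at 90 days. At least 1 KRT8 count was found in 50.7%, 1.49%, 61.7% and 1.78% of Sertoli-like cells in order of age, at median depths of 5609, 3723.5, 5493 and 5104.5 counts. T or NK-like cells, which should lack it, had shares of 4.02%, 0.897%, 2.82% and 0.306% at median depths of 2791, 1389, 1561 and 1280 counts. With each cell thinned to 2000 counts and shallower cells left out, the Sertoli-like shares were 24.1%, 0.558%, 37.2% and 0.495%. The thinned T or NK-like shares were 2.45% at 7 days and 2.04% at 30 days, with no such cell among 59 at 60 days and 79 at 90 days.

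**Figure D2:**
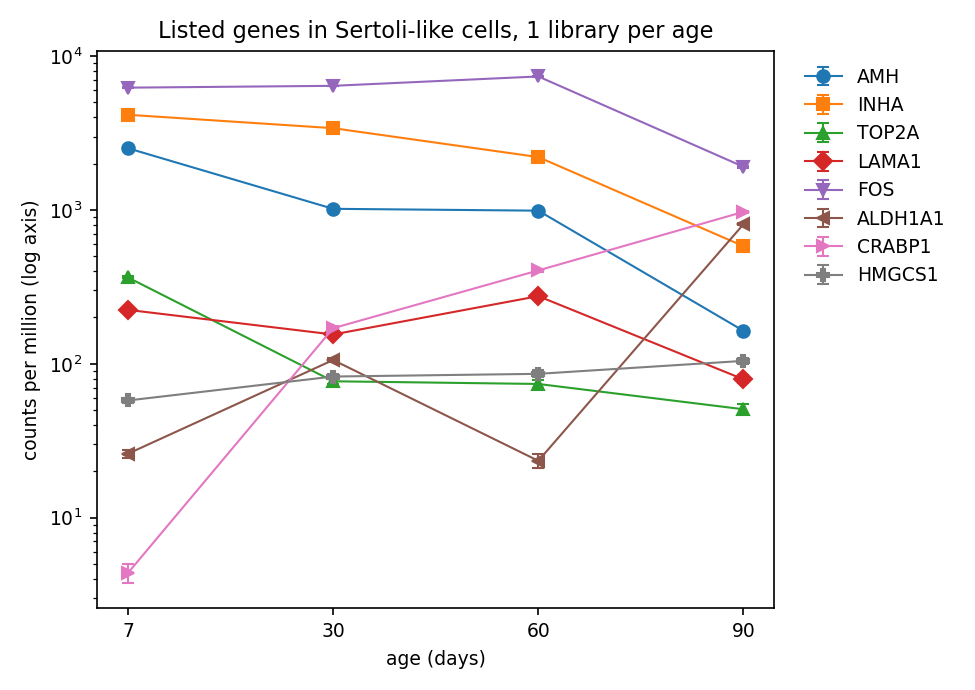
Expression of 8 genes in Sertoli-like cells (CPM of the summed counts, log y axis) against age in days (x axis, ages at equal steps, 1 library each), with exact 95% Poisson intervals as error bars, for counting error only. AMH goes from 2517 CPM at 7 days to 164 at 90 days and CRABP1 from 4.37 to 972.

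**Figure D3:**
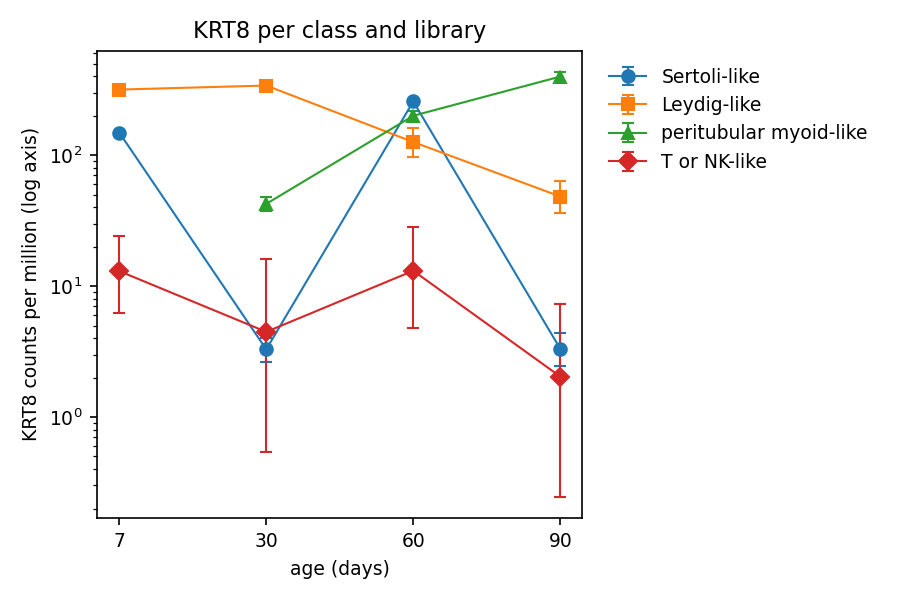
KRT8 in Sertoli-like, Leydig-like, peritubular myoid-like and T or NK-like cells (CPM of the summed counts, log y axis) against age in days (x axis, ages at equal steps, 1 library each). Error bars are exact 95% Poisson intervals for counting error only. In Sertoli-like cells the values at 7 and 60 days, 149 and 257 CPM, stand far above those at 30 and 90 days.

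In Leydig-like cells, CYP17A1 and CYP11A1, core enzymes of steroid synthesis, stayed abundant at all ages, while STAR and CYP19A1 were lower at 90 than at 7 days. CYP17A1 was 12064 CPM at 7 days, 14482 at 30 days, 3618 at 60 days and 8820 at 90 days, a log2 ratio of −0.45 (−0.48 to −0.42) for 90 against 7 days. STAR, which carries cholesterol into mitochondria, was 4802, 1673, 254 and 997 CPM at the 4 ages in order. FMO1, a flavin monooxygenase, was 14.9 CPM at 7 days and 1146 at 90 days, a log2 ratio of 6.26 (5.94 to 6.61), and CKB, the brain creatine kinase, was 474 and 6.38 CPM, a log2 ratio of −6.22 (−7.53 to −5.17). The comparison set 297 cells with 1096658 counts against 498 cells with 5433841 counts. TMM scaling moved every ratio by −0.59, and the median over 12584 measured genes was 0.45.

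Leydig-like cells of 7 and 30 days shared a cluster, those of 90 days had one of their own that FMO1 leads, and most of the 60-day cells lay in another. These clusters scored 4.04, 2.52 and 1.90 as Leydig in that order (mean log2 folds over the markers). The last held 150 of the 183 cells at 60 days, so steps to and from 60 days are also steps between clusters. The median depth per cell was 9429.5, 5258, 2196 and 3465 counts in order of age.

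Of 15 steroidogenesis genes, 5 were lower and 1 was higher, with a median of −0.44 at percentile 9.88, and 13 were lower with a median of −1.03 under TMM factors. The list's median was −1.18 in all other cells, and 8 members also served as markers of the class. CYP19A1, the aromatase that makes oestrogen, had −2.57, and STAR had −2.27. FDX1, which passes electrons to the steroid hydroxylases of mitochondria, had −2.19, and SCARB1, a lipoprotein receptor, −1.88. The higher member was SRD5A1, a steroid 5-alpha reductase, at 2.89, from 14.2 CPM to 105. LHCGR, the receptor of LH, had −0.26. Of 22 cholesterol genes, 8 were lower and 5 higher with a median of −0.35, and 12 were lower and 2 higher with a median of −0.94 under TMM factors. EBP, a sterol isomerase, had −2.34 and INSIG1, which holds sterol synthesis back, 2.31. The main median became 0.08 with the stricter cell filter and −0.14 with each cell thinned to 2000 counts.

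Beside FMO1, the largest increases were NDRG4, TM4SF1, ZNF503, SAMD5, RNASE4, SERPINB6, C1QTNF1, CADM1 and AEBP1. RNASE4, a secreted ribonuclease, was 29.8 CPM at 7 days and 656 at 90 days, with a log2 ratio of 4.46 in this class and −0.32 in all other cells. CADM1, a cell adhesion molecule, had 3.86, or 5.94 with 10% free RNA subtracted, and −0.50 in all other cells. Beside CKB, the largest decreases were IGFBP2, NRK, C3, COX4I2, KIT, CALD1, FBP2, GSTA1 and TMEM229A. GSTA1, a glutathione transferase, was 5104 CPM at 7 days, 4769 at 30 days, 1176 at 60 days and 742 at 90 days. KIT, the receptor of stem cell factor, was 184 CPM at 7 days and 5.83 at 30 days, and its log2 ratio for 90 against 7 days was −4.20. IGFBP2, which binds insulin-like growth factors, had −4.86, and C3, the central complement protein, −3.99. TMEM229A had 3 counts at 90 days and a log2 ratio of −4.21 (−6.50 to −2.65).

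Of 20 cell cycle genes, 14 were lower and 1 was higher, with a median of −1.22, and TOP2A had −2.20. Of 18 nuclear-encoded genes of oxidative phosphorylation 6 were lower and none was higher, with a median of −0.46, and 17 were lower with a median of −1.05 under TMM factors. Of 17 antioxidant genes 8 were lower and 3 higher, or 12 and 3 with TMM factors, with GSTO1 at −2.81 and NQO1 at 2.44. Of 12 junction genes, 10 were higher and none was lower, or 5 and none with TMM factors. The median was 1.28, or 3.23 with free RNA subtracted. It was also 1.97 in T or NK-like, 1.15 in pericyte-like or vascular smooth muscle-like, 0.77 in interstitial stromal-like and 0.71 in macrophage or monocyte-like cells. Spermatogonia-like cells had 0.03 and endothelial-like cells −0.15. In Leydig-like cells CLDN11, a tight junction claudin, was 47.9 CPM at 7 days, 506 at 60 days and 145 at 90 days. Of 15 immediate early genes 6 were higher and none was lower with a median of 0.56, but the median was −0.03 with TMM factors, 0.24 with the stricter cell filter and 0.37 without doublet removal. It was 1.10 with free RNA subtracted, with 11 higher, and 1.23 with only the expected doublets removed. KLF4, DUSP1 and FOSB had 2.54, 2.05 and 2.03.

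From 7 to 30 days the largest increases were PERP, FMO1 and AGPAT2 and the largest decreases KIT, SHISAL1 and NUDT16. From 30 to 60 days CXCL10, ROBO2 and EGR1 had the largest increases and CKB, TOP2A and IDI1 the largest decreases, with a log2 ratio of −3.76 for TOP2A. From 60 to 90 days RDH12, SLC16A10 and ALAS1, the last the first enzyme of haem synthesis, led the increases at 3.07, 3.21 and 3.09, from a low at 60 days. RDH12 was 1819, 1937, 268 and 2251 CPM at the 4 ages in order, SLC16A10 214, 215, 44.0 and 408, and ALAS1 1661, 291, 52.0 and 443. ABI3BP had no count at 90 days and was at least 29.2-fold lower. CXCL10, an interferon-induced chemokine, had 1 count at 90 days and a log2 ratio of −7.02 (−12.34 to −4.48), and IGFBP2 had −4.91.

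In peritubular myoid-like cells, the contraction genes of smooth muscle were all higher at 90 than at 30 days, the first age with enough cells, but the cells of these ages came from clusters with different marker scores. MYH11, the smooth muscle myosin heavy chain, was 490 CPM at 30 days, 377 at 60 days and 4847 at 90 days, a log2 ratio of 3.31 (3.25 to 3.36) for 90 against 30 days. ACTA2, the smooth muscle actin, was 2186, 2137 and 9114 CPM, a log2 ratio of 2.06 (2.03 to 2.09). ELN, which encodes elastin, was 7.29, 9.63 and 130 CPM, a log2 ratio of 4.15 (3.70 to 4.63). ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 1094, 395 and 29.0 CPM, a log2 ratio of −5.24 (−5.70 to −4.80). The comparison set 656 cells with 1480852 counts against 3134 cells with 6996185 counts. TMM scaling moved every ratio by −0.51, and the median over 14591 measured genes was 0.37.

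Cells of 30 and 60 days shared a cluster with no myoid marker among its leading genes, which scored higher as stromal (a mean log2 fold of 1.25 over the markers) than as myoid (1.04). Of the 656 cells of 90 days, 647 formed another, which NPTX1, MYH11, ACTA2 and MFAP4 lead and which scored 3.46 as myoid and 0.404 as stromal. All 16 smooth muscle genes were at least 1.5 times higher, with a median of 1.57, and 13 of them with TMM factors, with a median of 1.06. The median of this list in all other cells was −0.19. Since 9 of the 16 also served as markers, their count is not independent of how the cells were named. CNN1, the actin-binding calponin, had a log2 ratio of 4.08 in the class and −1.51 in all other cells, and MYL9 and MYLK, the light chain and its kinase, 2.49 and 2.26.

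Of 19 extracellular matrix genes, 8 were higher and 2 were lower with a median of −0.09, against 5 and 10 with a median of −0.60 under TMM factors. Without doublet removal 6 were lower and the median was −0.40. POSTN, MFAP4 and FBLN5, which go with elastic and fibrillar matrix, had 4.03, 3.23 and 2.003. LUM, a collagen-binding proteoglycan, was 2299 CPM at 30 days and 445 at 90 days, a log2 ratio of −2.37, and FBLN1 had −1.18. COL1A1, a chain of type I collagen, had −0.01. Basement membrane genes were split, with 4 of 14 higher and 2 lower, or 2 and 5 with TMM factors, among them LAMA5 at 2.24 and LAMA1 at −1.63.

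Among the largest increases were SPACA4, CCIN, NPTX1, LIMS2, PAPPA2, CNN1, TTLL7, ELN and RASSF3. SPACA4 and CCIN are sperm genes, with 0 and 1 count at 30 days and 62.1 and 68.2 CPM at 90 days. SPACA4 was at least 145-fold higher, and the log2 ratio of CCIN was 8.90 (6.39 to 14.22). In spermatid-like cells of the same library they stood at 397 and 511 CPM, and in T or NK-like cells at 71.3 and 92.7 CPM. NPTX1, a neuronal pentraxin, was 14.0, 12.3 and 1079 CPM at 30, 60 and 90 days, and its log2 ratio in all other cells was 4.65. LIMS2, a focal adhesion protein, had 5.89, and PAPPA2, a protease that cleaves IGF binding proteins, 6.05, with 0.08 in all other cells.

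The 10 largest decreases were KISS1, ANGPTL4, CEBPD, ADAMTS4, GADD45A, HAS1, C7, CISH, SOCS3 and CCL2. KISS1, the precursor of kisspeptin, was 72.9 CPM at 30 days and had no count at 90 days, at least 36.0-fold lower. SOCS3 and CISH, feedback inhibitors of cytokine signalling, had −3.18 and −4.22, and GADD45A, a DNA damage response gene, −4.36. ADAMTS4, a protease of aggrecan, and HAS1, a hyaluronan synthase, had 3 counts each at 90 days and log2 ratios of −5.69 (−7.97 to −4.14) and −4.88 (−7.17 to −3.33). These 10 genes were also lower in all other cells of the same libraries, by log2 ratios from −3.64 for CEBPD to −1.09 for CCL2.

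Of 20 cell cycle genes, 15 were higher and none was lower, or 13 and none with TMM factors, with a median of 2.11 in this class and 0.88 in all other cells. The median was 0.45 with the stricter cell filter, 1.04 over members with at least 100 counts and 3.49 with free RNA subtracted. TOP2A was 17.3 CPM at 30 days and 107 at 90 days, and BUB1 and CCNB2 had 5.07 and 4.51. Meiotic and haploid germ cells of the same library also express such genes. A cluster that TOP2A and other cell cycle genes lead was named interstitial stromal, with 277 cells at 30 days and 24 at 90 days. Whether it held dividing myoid-like cells was not tested, so the low level at 30 days may in part come from the clustering. Of 16 immediate early genes, 11 were lower and 1 was higher, or 13 and 1 with TMM factors, with a median of −1.30, MYC at −3.97, FOS at −1.52 and DUSP1 at 1.23. Of 22 cholesterol genes 12 were higher and 1 lower with a median of 0.71, or 6 and 5 with a median of 0.20 under TMM factors. With the stricter cell filter the median was 0.45. Of 21 TGF-beta superfamily genes 8 were higher and 8 lower, or 3 and 9 with TMM factors, with LTBP1 at 1.88 and ID3, a target of BMP signals, at −3.10.

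From 30 to 60 days ISG15, SPOCK1 and HAPLN1 had the largest increases, at 2.63, 2.78 and 2.40, and KISS1, FN1 and CEBPD the largest decreases, at −2.17, −1.80 and −1.66. From 60 to 90 days the largest increases included NPTX1 at 6.45 and CCIN at least 59.0-fold. The largest decreases of that step were HAS1, C7, a terminal complement protein, and ADAMTS4, at −5.90, −5.29 and −5.39.

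**Figure D4:**
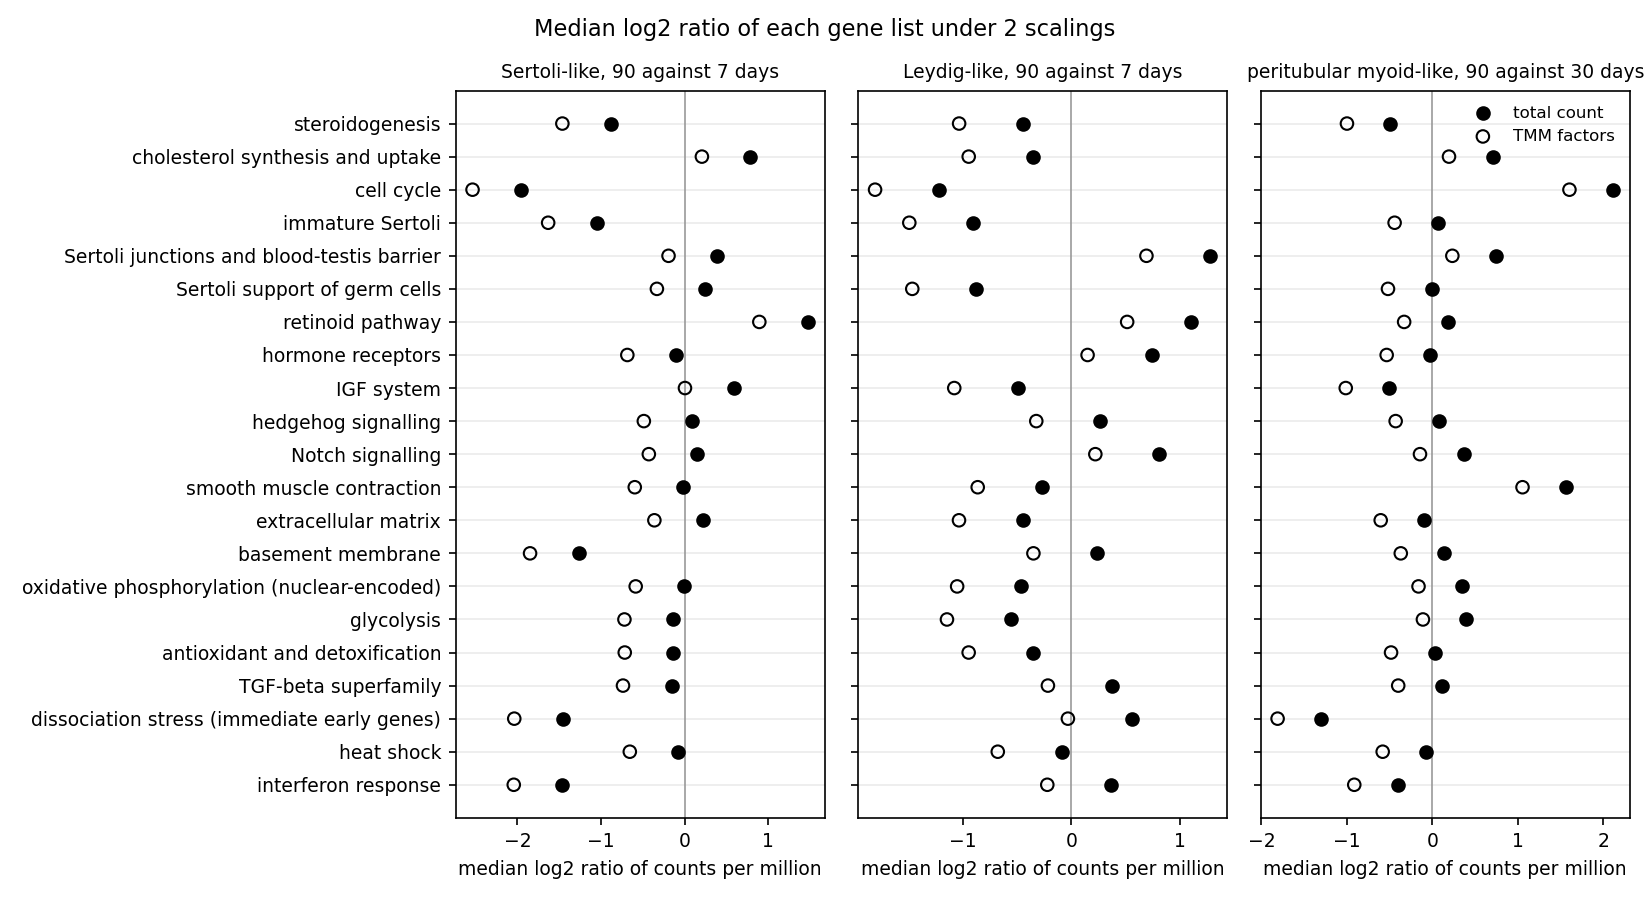
Median log2 ratio of each of 21 gene lists (x axis) in Sertoli-like and Leydig-like cells at 90 against 7 days and in peritubular myoid-like cells at 90 against 30 days, scaled by total counts (filled points) and by TMM factors (open points). TMM factors move medians down by a constant of −0.58, −0.59 and −0.51 in that order, which turns the sign of several medians, such as the Leydig-like immediate early genes, from 0.56 to −0.03.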

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

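Of the tests given here, all were chosen only after the result was seen, except the test for droplets that hold a myoid cell and a spermatid, the test for a small subset of KRT8-rich cells and the test of depth for the immediate early genes. The test for a dissociation shift was also replaced after its results were seen, from the Leydig-like median, by which the pattern was picked, to the medians of 6 other classes, which had been seen too. Limits on list percentiles, by which differences between classes were picked, and the intervals of the percentages that stayed, were likewise set after seeing the data.

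The immediate early genes moved apart between classes, with a list median of −1.46 in Sertoli-like and 0.56 in Leydig-like cells at 90 against 7 days, a difference of 2.01 that was not itself tested. A dissociation shift shared by all cells of a library is argued against as the whole cause of the Sertoli-like value, since the medians of 6 other classes, from −0.56 in interstitial stromal-like to 0.44 in T or NK-like cells, lay above it by 1.16 (1.01 to 1.30) in the median, only just past the bound of 1, while all cells that were not Sertoli-like, pooled with their changing mix of classes, had −1.28. With each cell thinned to 2000 UMIs, 94.4% (83.5 to 115%) of the difference stayed, and the named genes moved by 0.341 in the median. Thinning keeps the expected proportions within each cell, so it changes only the weight of deep cells and leaves out the shallowest. A larger weight of deep cells is thus argued against as the whole cause, and other effects of depth are left open. Among cells with at least 1000 detected genes and at most 10% mitochondrial UMIs, 89.1% of the difference stayed. The lower end of its interval (72.8 to 92.3%) passes the bound set for it, so a part of shallow or damaged cells is left open. A difference between the classes in how they respond to age, or in how each class responds to dissociation, may remain and cannot be separated with 1 library per age.

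KRT8 in Sertoli-like cells was high at 7 and 60 days and low at 30 and 90 days, a shape picked after looking over the 4-age profiles of the named genes. Free RNA in the 60-day library is argued against, since the median KRT8 level of 4 other classes was 7.20% of the Sertoli-like level. Endothelial-like cells (13.3, 1.74, 49.1 and 4.84 CPM in order of age) also went down, up and down at lower levels. However, 91 of the 167 endothelial-like cells at 60 days lay in a cluster that scored 1.08 as Sertoli and 1.03 as endothelial. The 60-day value of this class may thus hold KRT8 of Sertoli-like cells. KRT8 also went down, up and down in T or NK-like cells (13.0, 4.47, 13.1 and 2.04). The same held for spermatogonia-like, macrophage-like, B or plasma-like, pericyte-like and vascular smooth muscle-like cells, several of them on few counts. Stromal-like cells, at 21.2, 7.08, 22.4 and 73.7 CPM, went down and up as well, but further up at 90 days. A shift of the whole library is argued against as the whole cause by that last step of the stromal-like cells and by the Leydig-like cells. Their log2 ratio was 0.10 (−0.00 to 0.21) for 30 against 7 days in Leydig-like cells. A small subset of cells does not carry the 60-day value, since the 5% of cells with the most KRT8 held 23.4% of its counts, against 18.2% in Poisson draws. A difference between the animals, or one of age, may lie behind it and remains an untested hypothesis.

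The sperm genes SPACA4 and CCIN stood among the largest increases of peritubular myoid-like cells at 90 days. Free RNA from spermatids is a candidate explanation: the genes' CPM in myoid-like over spermatid-like cells was 0.145 in the median, 1.51 times the 0.0960 of 10 spermatid markers. Droplets that hold a myoid cell and a spermatid are argued against, because the 5% of cells with the most spermatid marker counts held 11.3% of these counts, against 11.7% in Poisson draws. For expression by the myoid cells themselves the outcome depended on the class compared. The 2 genes stood at 0.803 times their level in T or NK-like cells, a class chosen after the data were seen. SPACA4 and CCIN, at 62.1 and 68.2 CPM in myoid-like cells, were lower in several other classes. They were 25.9 and 28.6 CPM in Sertoli-like, 27.4 and 37.4 in Leydig-like and 38.3 each in endothelial-like cells. Other classes were closer, with intervals that overlap those of myoid-like cells. SPACA4 and CCIN were 49.99 and 58.6 CPM in interstitial stromal-like and 59.4 and 47.5 in pericyte-like or vascular smooth muscle-like cells. From T or NK-like over myoid-like, endothelial-like and Leydig-like to Sertoli-like cells, the spermatid gene TNP1 fell in the same order. The lower classes are thus no sign of expression by the myoid cells. A part from the myoid cells themselves was not ruled out and is left open.

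The cholesterol list also differed between the classes, with a median of −0.35 (percentile 1.43) in Leydig-like and 0.79 (percentile 99.57) in Sertoli-like cells, a difference of −1.14 that was not tested.

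The shallow mixed clusters were in none of the compared classes, but they counted among all other cells. They made up 31.7% of the used cells of the 60-day library. They held more of the neutrophil granule genes AZU1 (165 CPM, against 1.21 in the rest of that library), PRTN3 (98.1 against 0.732) and S100A12 (341 against 12.6), and more of the meiotic gene SYCP1 (62.6 against 8.42).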

How the results depend on the processing

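The alternatives with only the expected doublets removed and without the 60-day library were chosen only after the results were seen. With 1 library per age no result could be set against a spread between animals, and no age could be left out with a replicate in its place. No paired analysis was possible because no label ties the libraries to each other. The smallest niche class sum in a comparison, the Leydig-like one at 60 days, held 499959 counts. The direction of all 60 named genes was kept under each of the settings run for them, with 76 of 660 values moved, the furthest by 5.06 with free RNA subtracted. These genes were picked for the largest ratios in the same data, so a kept direction was close to given and is no check of it. Of 822 values of 69 list results, 618 stayed close, 190 moved and 14 reversed, and of 170 values of 25 share results 99 stayed close, 66 moved and 5 reversed. A list median counts as reversed only where its sign turned and the interval of its main value excludes 0, and 78 list medians turned sign in all, 19 of them with TMM factors. The cause was not tested for any of the values below.

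The Sertoli-like share differed by −32.5 percentage points between 90 and 7 days, by −34.1 without doublet removal, −37.7 with the strict cell filter, −28.7 at resolution 2, −40.8 with each library on its own and −34.4 without the 60-day library. The Leydig-like difference of −1.30 reversed to 0.346 with the strict filter. The myoid-like difference between 90 and 30 days, −14.7, was −12.0 without doublet removal, −9.89 with the strict filter and −15.6 with expected doublets removed. The spermatogonia-like difference of −1.12 reversed to 12.3 with the strict filter, 13.8 at resolution 0.5, 0.160 with each library on its own and 10.9 without the 60-day library. For all germ cells 30.1 became 31.2 with expected doublets removed and 31.8 without the 60-day library.

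In Sertoli-like cells the immature Sertoli median, −1.05, was −0.75 after thinning. Its higher members, 1, were 2 at resolution 2, with each library on its own, with expected doublets removed and without the 60-day library, and 0 after thinning, with TMM factors and with at least 100 counts. The junction median, 0.39, was −0.19 with TMM factors, which also turned the medians of Sertoli support to −0.33, hedgehog to −0.49, Notch to −0.43 and extracellular matrix to −0.36. The IGF median, 0.58, was −0.77 without doublet removal, −2.03 with the strict filter and −1.64 with at least 100 counts. In Leydig-like cells the steroidogenesis median, −0.44, was −0.56 without doublet removal, −0.35 with the strict filter, as a mean over cells and after thinning, and −1.03 with TMM factors. Its higher members, 1, were 2 with free RNA subtracted and after thinning, and its lower members, 5, were 13 with TMM factors. The cholesterol median of −0.35 was 0.082 with the strict filter, and the Notch median of 0.81 was −0.35 with it and −0.038 with at least 100 counts. TMM factors reversed the TGF-beta median to −0.22, the immediate early median to −0.031 and the interferon median to −0.22, and turned the hedgehog median to −0.32 and the basement membrane one to −0.35.

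In myoid-like cells the extracellular matrix median, −0.09, was −0.40 without doublet removal, −0.17 with the strict filter and without the 60-day library, −0.16 as a mean over cells and −0.60 with TMM factors. Its 8 higher members were 5 with TMM factors, and its 2 lower ones 6 without doublet removal and 10 with TMM factors. The steroidogenesis median of −0.49 was 0.64 with free RNA subtracted. TMM factors reversed the medians of hedgehog to −0.43, oxidative phosphorylation to −0.16 and glycolysis to −0.11, and turned those of Notch to −0.14, basement membrane to −0.37, TGF-beta to −0.40, the retinoid pathway to −0.33, immature Sertoli genes to −0.44 and antioxidant genes to −0.48.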

Other observations

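The comparison of library orders was chosen only after the data were seen.

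Other classes with at least 100 cells in 2 libraries differed too, again with no replicate check, and TMM factors were not computed for them. Macrophage or monocyte-like cells, 586 at 7 days and 122 at 90 days, had less SPP1, which encodes osteopontin, with 1745 CPM at 7 days, 583 at 30 days, 94.6 at 60 days and 5.82 at 90 days. SPP1 leads a cluster of this class that held 220 of its cells at 7 days and 1 at 90 days. APOE, the lipoprotein that macrophages secrete, was 1624 and 46.6 CPM at 7 and 90 days. VCAM1, an adhesion molecule, had a log2 ratio of −5.14. Of 16 interferon response genes in these cells 14 were lower and none was higher, with a median of −1.35 here and −1.28 in all other cells. The median was also −0.98 in interstitial stromal-like and −0.83 in endothelial-like cells, but 0.37 in Leydig-like cells. Endothelial-like cells had more RGS5, a gene also known from pericytes, at 31.6 CPM at 7 days, 224 at 30 days, 870 at 60 days and 423 at 90 days, and less RBP7, a retinol-binding protein, at 301 CPM at 7 days and 21.2 at 90 days. The class includes a deep cluster with a score of 1.69 for pericyte markers, with 4, 32, 12 and 62 cells in order of age. At 60 days, the age of the RGS5 peak, that was 12 of 167 cells. Another 91 of the 167 lay in a cluster that scored 1.08 as Sertoli and 1.03 as endothelial. In interstitial stromal-like cells IGFBP2 had −4.12 and DPT, a matrix protein, −4.13, while NPTX1 had 11.20. Of these cells 3150 of 3473 at 7 days lay in one cluster and 2000 of 2118 at 90 days in another, which NPTX1 leads. In lymphatic endothelial-like cells SCG3, a granin, had no count in the 94 cells at 7 days and was 902 CPM at 30 days, 870 at 60 days and 134 at 90 days.

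Spermatogonia-like cells, 538 at 7 days and 354 at 90 days, had more ATP2B4, a calcium pump, and LZTS1, with log2 ratios of 3.26 and 3.24, and more CRABP1 at 2.82. CSRP2, FGF8 and STMN2 had −3.62, −3.47 and −3.39. The 7-day cells lay in a pair of clusters, with 307 and 231 cells, that FGF8 and STMN2 lead, and 316 of the 90-day cells in another that LZTS1 leads. Of 22 cholesterol genes 10 were higher and 2 lower in these cells, with a median of 0.67, and of 20 cell cycle genes 13 were lower and none was higher, with a median of −0.92. Of 11 heat shock genes 7 were lower and none was higher. In pericyte-like or vascular smooth muscle-like cells 13 of 15 smooth muscle genes were lower at 90 than at 7 days and none was higher, with a median of −1.19. This class was a single cluster with RGS5 and KCNJ8 among its leading genes. The vascular smooth muscle-like cluster kept apart, with MYH11 and TAGLN among its leading genes, was not part of it. That cluster held 68 cells at 7 days and 254 at 90 days, so the result does not cover it.

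In the 90-day library TNP1, a transition protein of spermatids, stood at 12798 CPM in spermatid-like cells, 1929 in T or NK-like, 1265 in peritubular myoid-like, 898 in endothelial-like, 776 in Leydig-like and 705 in Sertoli-like cells.

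Between 7 and 90 days, 27.2% of 4382 genes in Sertoli-like cells went one way over the ages as labelled, and 14.8% with the 30-day and 60-day libraries exchanged.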
